A study of Drosophila melanogaster with 2 samples.

How the data were processed

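ATAC-seq was done on Drosophila S2 cells, a line grown at 25°C in a serum-supplemented insect medium, per the labels. Each of the 2 libraries was made from 2000000 cells tagmented with Tn5 and amplified for 12 cycles. The submitters' processing notes list Bowtie2 (an aligner), MACS2 (a peak caller), deepTools and the genome build dm6, with no versions, order or settings. Names of the peaks carry the words macs2 and fragments. Whether the 2 libraries were pooled before peaks were called, how fragments were filtered or shifted for the transposase's offset, and how duplicates and reads of repeated sequence were treated are not given in the sources used here. Each of these can move a peak's position by a few bases or change its height. The total depth of each library is unknown, and values per library were not used here.

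The deposited peak list has 1 line per summit. Its score column, as deposited, was the whole part of 10 times the −log10 of the q-value in 35534 lines and off by 1 in the other line, and was not used further. The fold enrichment column, as deposited, is a ratio of the summit's pileup to the caller's local background, each with a pseudocount of 1. The −log10 p and −log10 q columns were also used as deposited by the authors, and the lowest −log10 q was 1.30. Interval bounds and summit offsets are in bp, and positions are given here counted from 1. In 65 lines no summit was placed and the interval's middle was used. The number of columns of samples left out was 0.

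The pileup and background were recovered from the fold and the −log10 p of each summit. The whole number of fragments and the background were solved that, under a Poisson upper tail with a pseudocount of 1 in the fold, gave both columns. A summit counted as recovered when the −log10 p was met within 0.001, and the largest residual was 0.000521. A background counted as the genome-wide value when it lay within 0.005 fragments of it. The name fragments comes from the names of the peaks, and extended reads in their place are not excluded. On simulated summits 3000 of 3000 pileups were recovered. Intervals of 95% on a pileup are exact Poisson intervals and cover counting error only, because PCR copies and Tn5 preference are not in them.

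Gene positions came from a RefSeq gene table of Drosophila Release 6 plus ISO1 MT, the assembly that dm6 names, with 17807 genes on 7 chromosomes, of which 13946 are protein-coding. That table gives the start and end of each gene without strand or transcripts. The analysis planned before the data were examined used windows of 250 bp around transcription starts. Windows of 250 bp to either side of either annotated gene end took their place, a peak counting for a gene when it overlapped a window by 1 bp or more. Classes by exon, intron and UTR became at a gene end, inside a gene and between genes, by the summit. The planned motif analysis, which needs a genome sequence, and the alternative with only a gene's 5′ start were not run.

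Shares carry exact (Clopper-Pearson) 95% binomial intervals. Summits were compared with 1000 shuffles within their own chromosome arm, with a 1-tailed p. Gene lists were tested with two-sided Fisher's exact tests of members against all other protein-coding genes, with Benjamini-Hochberg adjustment over 33 lists at 0.05. The lists were fixed before the data were examined and hold 1028 distinct matched genes, 5 of them in more than 1 list, while 4 members had no match. The roX1 and roX2 RNA genes count in the dosage compensation list, and Or10a and Gr10a have the same coordinates. A list's median pileup takes the highest peak at an end of each open member and is given as a percentile among 10000 random lists of the same size drawn from the 8421 open genes. Medians of summits were compared with two-sided permutation tests of 100000 resamples. The interval on the difference between X and autosomes is Newcombe's. On simulated data 182 of 200 changed lists of 15 or more genes (with 95% or 20% open against 60%) and 7 of 428 unchanged lists were called; smaller changed lists were not simulated, and the test of medians called 10 of 200 comparisons with no shift.

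Genes named in the text follow a rule fixed before the data were examined: all 8 homeotic genes and all PRC2 genes, in each other list the 2 open members with the highest fold and the first 2 by alphabet without a peak, the gene nearest to each of the 10 strongest summits, and the 5 protein-coding genes with most summits inside. A gene that this rule names among the ribosomal protein genes is not reported here. Other names, such as Myo81F and those at loci of high background, were chosen after their values were seen. The counts of gene lists in peak-free stretches, the tests of strength on X and of gene biotypes, and the search for loci of high background were also chosen after the data were examined. Alternatives were stricter peak thresholds (−log10 q of at least 10, and fold at or above the median), merged lines, and windows of 100 and 1000 bp. Further alternatives were summits required inside the window and 10000 draws of random genes matched on length in 20 bins. Those draws took genes outside the list from each bin, and their p is called a permutation p here. Isolated gene ends, with no other gene's end within 1 kb, a local shuffle of up to 50 kb, and the recovered pileup in place of the fold were added after the data were examined, as were the alternatives for the homeotic complexes. Alternatives used 200 shuffles each.

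Computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots were drawn with matplotlib 3.10.9.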

Results

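Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in Drosophila S2 cells, an embryo-derived line with features of hemocytes (fly blood cells). The series had 1 group of 2 libraries, each made from 2000000 cells with 12 cycles of PCR. Nothing in the labels says whether the 2 libraries came from separate cultures, and 1 list of peaks served the whole series. No comparison between groups of samples was therefore possible, and no peak had a replicate error. The comparisons below are between chromosomes, gene groups and regions within that list, and their p-values describe this list with genes or peaks as the units. The study was on inhibitors of PRC2, the Polycomb complex that methylates lysine 27 of histone H3, so Polycomb genes and the homeotic complexes were among the groups examined.

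The list held 35535 summits in 28292 intervals, of which 23118 had 1 summit and 5174 had several, up to 8. The intervals covered 5.09 Mb, which was 3.70% of the 137 Mb spanned by chromosome arms 2L, 2R, 3L and 3R and chromosomes 4, X and Y. Their median width was 139 bp (quartiles 92 and 217 bp, range 60 to 1366 bp). The fold enrichment, which is the authors' own value for each peak, had a median of 3.61 and ranged from 1.23 to 103. The depth of each library was not known from the list, but the pileup at each summit, the number of overlapping fragments as the peak caller counted them, was recovered as a whole number for 35535 of 35535 summits. The unit is called fragments here from the names of the peaks, and whether the caller piled up whole fragments or extended reads was not settled. If mates of a pair were counted separately, the counting errors and intervals given are too narrow. The median pileup was 56 (quartiles 33 and 109, range 20 to 3294), which gives a counting error of 13.4% at the median, 17.4% at the lower quartile and 9.58% at the upper quartile. These errors and the intervals below cover counting error only. The local background against which the caller tested each summit lay within 0.005 fragments of its genome-wide value of 9.91 for 10996 summits (30.9%). No summit had a background below that range. The median background was 12.5 and the highest, on 3L, was 328.

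**Figure D1:**
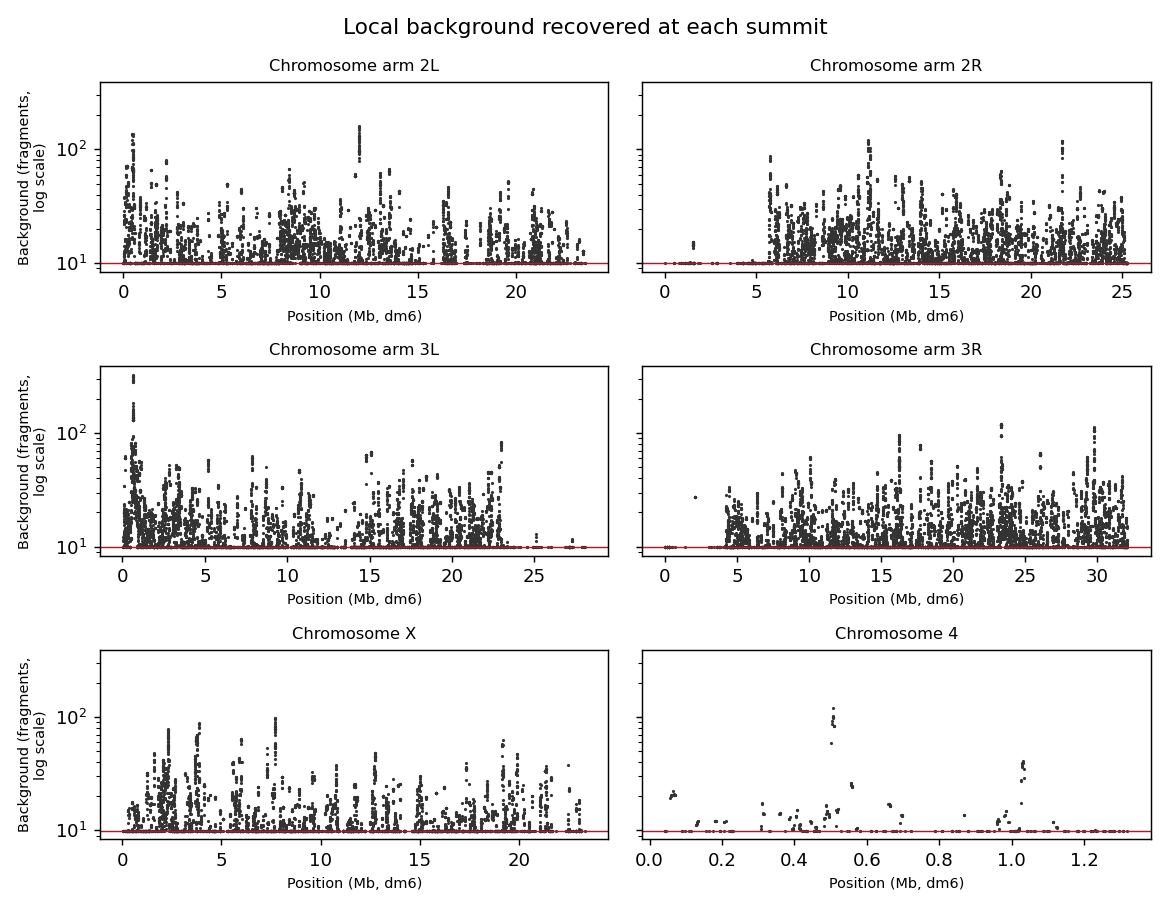
Local background recovered at each summit (fragments, log scale) along each chromosome arm (Mb, dm6), 1 point per summit, with the genome-wide value of 9.91 as a red line; chromosome Y is left out. Most arms have narrow peaks of background, the highest at the left end of 3L, where it reached 328.

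Accessible sites were concentrated at the ends of annotated genes. Within 250 bp of a gene end lay 10323 of the 35535 summits, or 29.1% (95% exact interval 28.6 to 29.5%), against 10.5% ± 0.161 (SD over 1000 shuffles) when summits were placed at random on their own arm. This was 2.77 times the shuffled share, and the 1-tailed permutation p = 0.001 was the smallest the shuffles could give. Summits farther inside genes made up 56.7% (62.0% in the shuffles) and summits between genes 14.3% (27.5% in the shuffles). Summits at gene ends were also stronger, with a median fold of 5.27 (quartiles 3.23 and 8.37) against 3.13 (2.29 and 5.32) for the 25212 others. The difference of 2.14 had p = 1e-05 in a two-sided permutation test of 100000 resamples, the smallest it could give. The median pileup was 76 at gene ends and 49 elsewhere, a ratio of 1.55. Gene ends include both the start and the finish of a gene, because strand was not used here, so these shares are not promoter shares. The ratio to the shuffles ran from 1.78 with a window of 1000 bp to 4.19 with 100 bp, and the difference in median fold fell to 1.00 among peaks at or above the median fold.

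Of 13946 protein-coding genes, 8421 had a peak within 250 bp of an end, or 60.4% (95% exact interval 59.6 to 61.2%). A peak lay at 1 end only in 6783 genes and at both ends in 1638 (11.7%). Neither a peak at an end nor a summit inside was found for 4682 genes (33.6%), and 843 had a summit inside but no peak at an end. Neighbouring genes often share an end region, and among the 5698 genes with an end more than 1 kb from every other gene's, 1727 (30.3%) had a peak there. Only isolated ends count in this share, so a gene can be scored on 1 end, and the set of genes differs. Its distance from 60.4% therefore does not measure the sharing of ends alone.

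Genes on the X chromosome had peaks at their ends about as often as autosomal genes. S2 cells carry out the male form of dosage compensation, in which genes of the X are transcribed at a raised level. The share was 60.3% of 2197 genes on X (58.2 to 62.4%) and 60.4% of 11645 genes on 2L, 2R, 3L and 3R (59.5 to 61.3%). The difference of -0.094 percentage points (95% interval -2.34 to 2.12) had p = 0.943 in a two-sided Fisher's exact test. On the small chromosome 4, 61 of 80 genes (76.3%, 65.4 to 85.1%) had such a peak, and on Y 1 of 24 did. The X result turned with the settings: among peaks at or above the median fold the share on X was higher by 2.65 points (exact p = 0.024), with a window of 1000 bp the difference was -3.59 points (exact p = 0.00069), and at isolated ends it was -3.07 points (exact p = 0.059).

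Peaks at gene ends on X had lower pileup and lower background than those on the autosomes. The median pileup was 70.5 over 1588 summits on X and 77 over 8640 on the autosomes (permutation p = 0.0014), and the median background was 9.95 against 12.6 (permutation p = 1e-05, the smallest possible). The median fold was higher on X, at 5.50 against 5.21 (permutation p = 0.021). At the genome-wide background lay 49.4% of the X summits (46.9 to 51.9%) and 25.2% of the autosomal ones (24.2 to 26.1%). That value is the lowest background in the list, so the medians can understate how much lower the background was on X. The copy number of X in these cells was not measured, and fewer copies would lower pileup and background alike. Over all summits, by contrast, the median pileup was 60 on X and 53, 59, 55 and 55 on 2L, 2R, 3L and 3R, a comparison not tested. Across all summits the density was lowest on X among the large arms, at 23.6 per 100 kb, against 28.7 on 2L, 27.6 on 2R, 26.6 on 3L, 26.2 on 3R and 26.9 on chromosome 4. These tests of strength on X were chosen after the data were examined.

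Genes encoding Polycomb proteins were open at their ends throughout. All 8 genes for subunits of PRC2 and its accessory factors had a peak at an end, against 60.4% of the other genes (adjusted p = 0.038, two-sided Fisher's exact test, Benjamini-Hochberg over 33 gene lists). The highest pileup was 350 (95% Poisson interval 314 to 389) at esc, which encodes the WD-repeat subunit that binds methylated histone H3. Then came jing, an AEBP2 relative, with 223 (195 to 254), Su(z)12 with 162, Caf1-55 with 146, E(z), the methyltransferase itself, with 121 (100 to 145), Jarid2 with 118, Pcl with 116 and escl, the paralog of esc, with 107 (87.7 to 129). The summit of E(z) lay at 3L 10638139, just past its annotated right end at 10638130, and that of esc at 2L 11829419, past its end at 11829405. Against random genes of matched length the PRC2 list was no longer called (8 open members against a mean of 5.48, adjusted permutation p = 0.13), nor was it with a window of 1000 bp (adjusted exact p = 0.16) or for its 2 members with an isolated end, which were higher by 19.7 points (adjusted exact p = 0.65).

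The other Polycomb and trithorax genes had similar shares. All 16 genes on the list of PRC1 and Polycomb recruiters had a peak at an end (adjusted exact p = 0.0011). It was led by Pc, whose chromodomain protein binds methylated H3, with a fold of 18.0 and a pileup of 203 (176 to 233). Next was Asx, a Polycomb-group gene outside both of these classes, with a fold of 16.0 and a pileup of 225. Of the 17 genes on the trithorax-group list 16 did (adjusted exact p = 0.0079), among them trx, an H3K4 methyltransferase gene, at a fold of 14.8. Trithorax-group genes counteract Polycomb silencing. The highest fold on the list, 20.5, was at ttv, a heparan sulfate synthesis gene that is not a trithorax-group gene but counts in this test. The 1 listed gene without a peak at an end was tna, which had 27 summits inside its 41.0 kb. Trithorax genes were not called with length-matched genes (adjusted permutation p = 0.074), among peaks at or above the median fold or with a window of 1000 bp (adjusted exact p = 0.18 and 0.09), nor were the 5 with isolated ends, which were higher by 49.7 points (adjusted exact p = 0.075). All 8 dosage compensation genes had a peak at an end (adjusted exact p = 0.038), led by msl-2, the male-specific subunit of the dosage compensation complex, with a fold of 17.6 at a summit shared with its neighbour ND-PDSW, and Clamp with 13.5. This list was not called either with length-matched genes (adjusted permutation p = 0.16), a window of 1000 bp (adjusted exact p = 0.16) or its 1 member with an isolated end, which was open (69.7 points, adjusted exact p = 0.45).

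**Figure D2:**
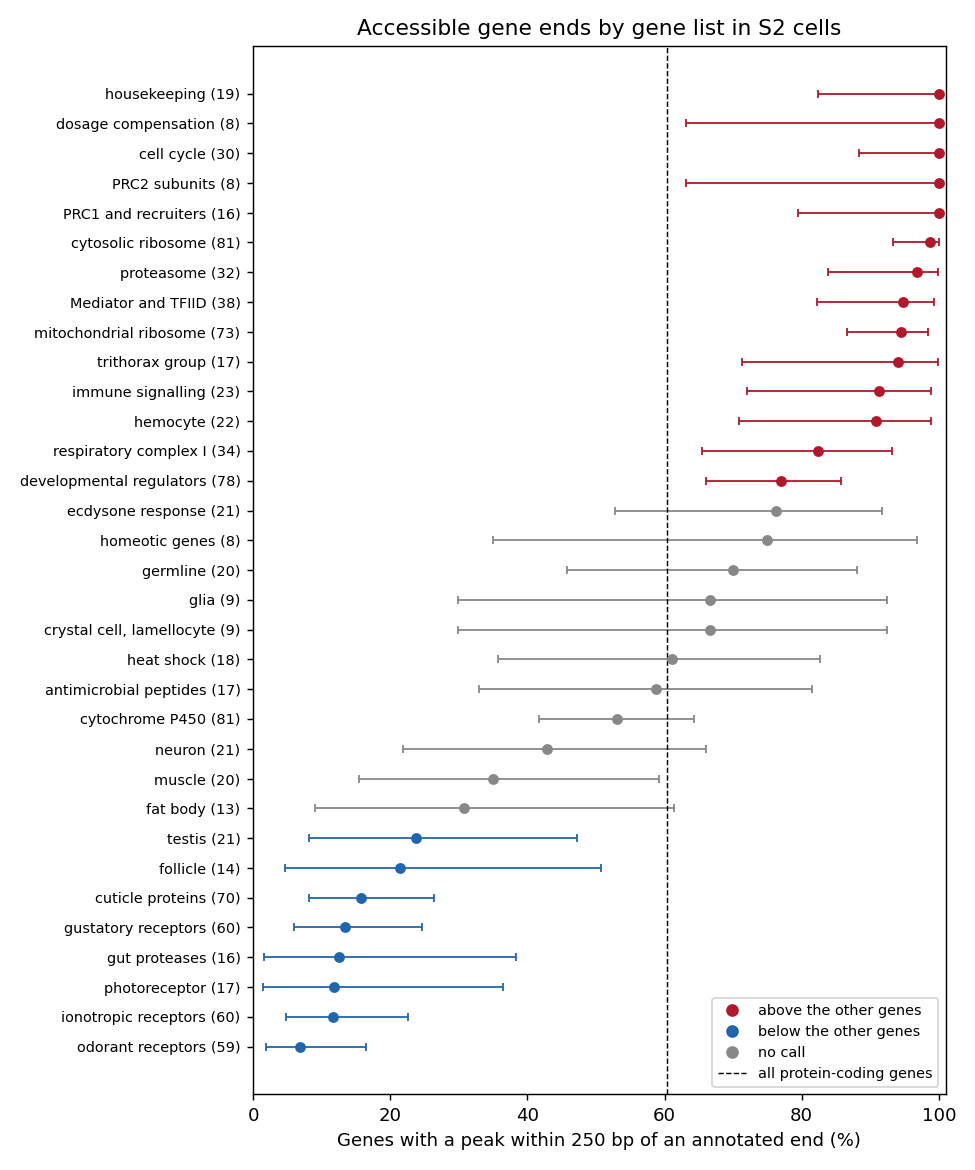
Share of genes with a peak within 250 bp of an annotated end (percent) in each of the 33 gene lists, with the number of members in brackets, exact 95% binomial intervals as bars, and the 60.4% of all protein-coding genes as a dashed line. Colour gives the call of Fisher's exact test: 14 lists lie above the other genes, 8 below, and 11 have no call.

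Genes for growth and basic cell functions had peaks at their ends in most cases. All 30 cell cycle genes had a peak at an end (adjusted exact p = 1.9e-06), with dup, a replication licensing factor, at a fold of 16.5 and CycA, a mitotic cyclin, at 13.9. So did all 19 housekeeping genes (adjusted exact p = 0.00023), led by the glycolytic gene Tpi at 15.5 and the proteasome ATPase gene Rpt1 at 12.9. Of 81 cytosolic ribosomal protein genes 80 did (98.8%, adjusted exact p = 1.8e-15), led by RpL15 at 26.0, with RpS10a, a paralog of RpS10b, as the exception. Of 73 mitochondrial ribosomal protein genes 69 did (94.5%, adjusted exact p = 2.3e-10), led by mRpS14 and mRpL48 at 16.8 and 16.0, with mRpL19 and mRpL20 among those without. Of 32 proteasome genes 31 did (adjusted exact p = 1.4e-05), led by Prosbeta6 at 18.8 and Prosbeta7 at 16.0, and Prosalpha1 did not. The Mediator and TFIID list had 36 of 38 (adjusted exact p = 9.8e-06), with MED20 at 15.6 and Taf1 at 13.9 leading at gene ends. MED6 and MED26 had no peak at an end but 4 and 2 summits inside, the strongest at folds of 11.4 and 19.7. The respiratory complex I list had 28 of 34 (82.4%, adjusted exact p = 0.013), led by ND-PDSW at 17.6 (the summit at 2L 3466113, which it shares with its neighbour msl-2) and ND-MLRQ at 14.5, with ND-20L and ND-23 among those without. Complex I was not called at or above the median fold (adjusted exact p = 0.083), and its 9 genes with isolated ends differed from the others by -19.2 points (adjusted exact p = 0.45). With few isolated ends, housekeeping genes (7) were higher by 41.2 points, mitochondrial ribosome genes (4) by 44.7 and Mediator and TFIID genes (5) by 9.70, without a call (adjusted exact p = 0.075, 0.16 and 0.73).

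Hemocyte genes and innate immune signalling genes were open more often than other genes. Of 22 genes on the hemocyte list 20 had a peak at an end (90.9%, 70.8 to 98.9%, adjusted exact p = 0.0066), including zfh1, a zinc-finger homeodomain gene, with a pileup of 682 (632 to 735) and eater, a phagocytic receptor gene, with 201. The median pileup of the open members was 101.5, at the 57.8th percentile of random lists of open genes. With matched lengths the call was kept narrowly (adjusted permutation p = 0.05). The 2 without were vkg, a type IV collagen gene that had 12 summits inside, and Fer2. Fer2 is a bHLH transcription factor gene and not an established hemocyte gene, but it counts in this test. Of 23 genes of the Toll, Imd and JAK/STAT pathways 21 did (91.3%, adjusted exact p = 0.0045), led by dome, the JAK/STAT receptor gene, at a fold of 22.1 and cact, the fly IκB gene, at 18.5. The exceptions, PGRP-LB and PGRP-SA, encode peptidoglycan recognition proteins. The call of this list was also kept narrowly with matched lengths (adjusted permutation p = 0.05). The antimicrobial peptide genes, the targets of these pathways, were not called, with 10 of 17 open (58.8%, adjusted exact p = 1). Their open members were weak apart from CecC, with a pileup of 353, and Mtk, with 104: the median of 43.5 was at the 0.135th percentile of 10000 random lists of open genes, whose overall median was 98. They are short genes, and against genes of matched length their share was higher by 28.9 points (adjusted permutation p = 0.031), while among peaks at or above the median fold it differed by -27.8 points (adjusted exact p = 0.041).

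Genes of most other cell types were open less often, or not detectably different. Photoreceptor genes had 2 of 17 open (11.8%, 1.46 to 36.4%, adjusted exact p = 0.00016), norpA and rdgA, while the arrestin genes Arr1 and Arr2 were without. Gut protease genes had 2 of 16 (adjusted exact p = 0.00031), Jon25Biii and Jon99Ci, with the trypsin genes alphaTry and betaTry without. Testis genes had 5 of 21 (23.8%, adjusted exact p = 0.0026), with topi and mia open and aly and can, which act in the meiotic arrest pathway with them, without. Eggshell genes of the follicle cells had 3 of 14 (adjusted exact p = 0.0079), among them Cp7Fb and Cp15 at pileups of 38 and 35, while Cp18 and Cp19 were without. The follicle list was not called with matched lengths (adjusted permutation p = 0.13) or a window of 1000 bp (adjusted exact p = 0.12). At isolated ends, where 30.3% of genes were open, the differences were -30.4 points for 10 photoreceptor genes and for 11 testis genes, -20.3 for 10 gut protease genes and -17.8 for 8 follicle genes, without a call (adjusted exact p = 0.084, 0.086, 0.45 and 0.59).

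Several marker lists had no call against the other genes. Muscle genes had 7 of 20 open (35%, adjusted exact p = 0.052), including Mef2, the muscle transcription factor gene, and Mlc2, and not Act88F or bt. Fat body genes had 4 of 13 (30.8%, adjusted exact p = 0.06), with apolpp, the lipophorin gene, at a fold of 23.3 and Obp99b at 4.77, and not Adh or Fbp1. Neuronal genes had 9 of 21 (42.9%, adjusted exact p = 0.16), led by elav, a neuronal RNA-binding protein gene, at 13.0 and nAChRalpha6 at 11.7, and not cac or CadN. With matched lengths muscle, neuron and fat body were called below (adjusted permutation p = 0.0085, 0.038 and 0.05), and with the summit required in the window so were muscle and fat body (adjusted exact p = 0.033 for each). Muscle was also called below at a −log10 q of at least 10, at or above the median fold and with a window of 100 bp (adjusted exact p = 0.02, 0.037 and 0.019). Glial genes had 6 of 9, led by moody at 17.2 and wrapper at 16.2, with alrm and Gs2 without (adjusted exact p = 1). Inside Gs2 lay 8 summits, the strongest with a pileup of 166, and inside alrm 0. Crystal cell and lamellocyte genes also had 6 of 9, led by Pu and lz at 19.7 and 11.7, with atilla and ItgaPS4 without (adjusted exact p = 1). Germline genes had 14 of 20 (adjusted exact p = 0.56), led by zpg and osk at 13.6 and 9.87, with AGO3 and bam without, and were called above with a window of 1000 bp (adjusted exact p = 0.041).

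The large chemosensory receptor and cuticle protein families were mostly without peaks at their ends. Odorant receptor genes had 4 of 59 open (6.78%, 1.88 to 16.5%, adjusted exact p = 1.4e-16), ionotropic receptor genes 7 of 60 (11.7%, adjusted exact p = 5.8e-14), gustatory receptor genes 8 of 60 (13.3%, adjusted exact p = 3.6e-13) and cuticle protein genes of the Cpr family 11 of 70 (15.7%, adjusted exact p = 1.3e-13). The strongest open members included Or46a and Or43a at folds of 11.1 and 3.21, Ir60b and Ir60e at 11.0 and 9.96, Gr63a and Gr98d at 7.56 and 7.33, and Cpr73D and Cpr50Cb at 7.16 and 7.04. Among those without were Or10a, Or13a, Ir10a, Ir100a, Gr10a, Gr10b, Cpr11A and Cpr100A. At isolated ends the gustatory list differed by -19.7 points without a call (adjusted exact p = 0.062, 28 genes). Open odorant receptor and cuticle genes were weak, with median pileups of 30 (0.165th percentile of random lists) and 33 (0.03rd percentile).

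Inducible gene families were mixed and had no call. Heat shock genes had 11 of 18 open (61.1%, adjusted exact p = 1), led by the small heat shock gene Hsp23 at a fold of 13.5 and Hsp68 at 12.1, with Hsp22 and Hsp70Aa without. The Hsp70 copies are nearly identical, so reads placed on them are uncertain. Cytochrome P450 genes had 43 of 81 (53.1%, adjusted exact p = 0.26), with Cyp6u1 and Cyp9c1 at 19.2 and 16.4 and Cyp28c1 and Cyp18a1 without. Against matched lengths the P450 share was below that of other genes (adjusted permutation p = 0.04). Genes of the ecdysone response had 16 of 21 (76.2%, adjusted exact p = 0.23), led by E23 and Eip63E at 25.3 and 19.2, with Blimp-1 and Cyp18a1 without. The median pileup of their open members, 224.5, was above all 10000 random lists of open genes.

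Homeotic genes and developmental regulators, textbook targets of Polycomb silencing, often had strong peaks at their ends. Of 78 developmental regulators 60 had such a peak (76.9%, 66.0 to 85.7%, adjusted exact p = 0.005), and the median pileup of 190 was above all 10000 random lists. The strongest were wg, a Wnt ligand gene, with a fold of 33.7 and a pileup of 429 (389 to 472), and caup, a homeobox gene of the Iroquois complex, with 30.5 and 412 (373 to 454), while bap and B-H2 were without. The share was not called with matched lengths (adjusted permutation p = 0.34) or a window of 100 bp (adjusted exact p = 0.095), while the 76 members with isolated ends were higher by 38.6 points (adjusted exact p = 2.4e-10). Of the 8 homeotic genes 6 had a peak at an end (75%, 34.9 to 96.8%), which did not differ detectably from the other genes (adjusted exact p = 0.56). At isolated ends, which all 8 have, they were higher by 44.8 points (adjusted exact p = 0.036). In that setting the genes compared with them differ, and 30.3% of all genes were open. With matched lengths and with a window of 1000 bp the homeotic genes were higher by 5.52 and 3.11 points, without a call. The median pileup of those 6, 235, was at the 99.7th percentile of random lists.

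Along the Antennapedia complex on 3R, lab had a pileup of 392 (354 to 433) at its right end and 30 at its left, and pb had 133 at its right end. Dfd had 208 (181 to 238) at its left end, and Scr had 262 (231 to 296) at the right end and 108 at the left. Antp had no peak within 250 bp of either end, but 11 summits inside, and its strongest summit within 5 kb, with a pileup of 439 (399 to 482), lay 1781 bp past its right end. In the bithorax complex, abd-A had 318 (284 to 355) at its right end, and Ubx had 62 (47.5 to 79.5) at its left end, 32 at its right end and a summit of 356 inside. Abd-B had no peak at an end and 11 summits inside, the strongest at 374 (337 to 414). Peaks covered at most 4.73% (lab) of any homeotic gene with 5 kb on either side.

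**Figure D3:**
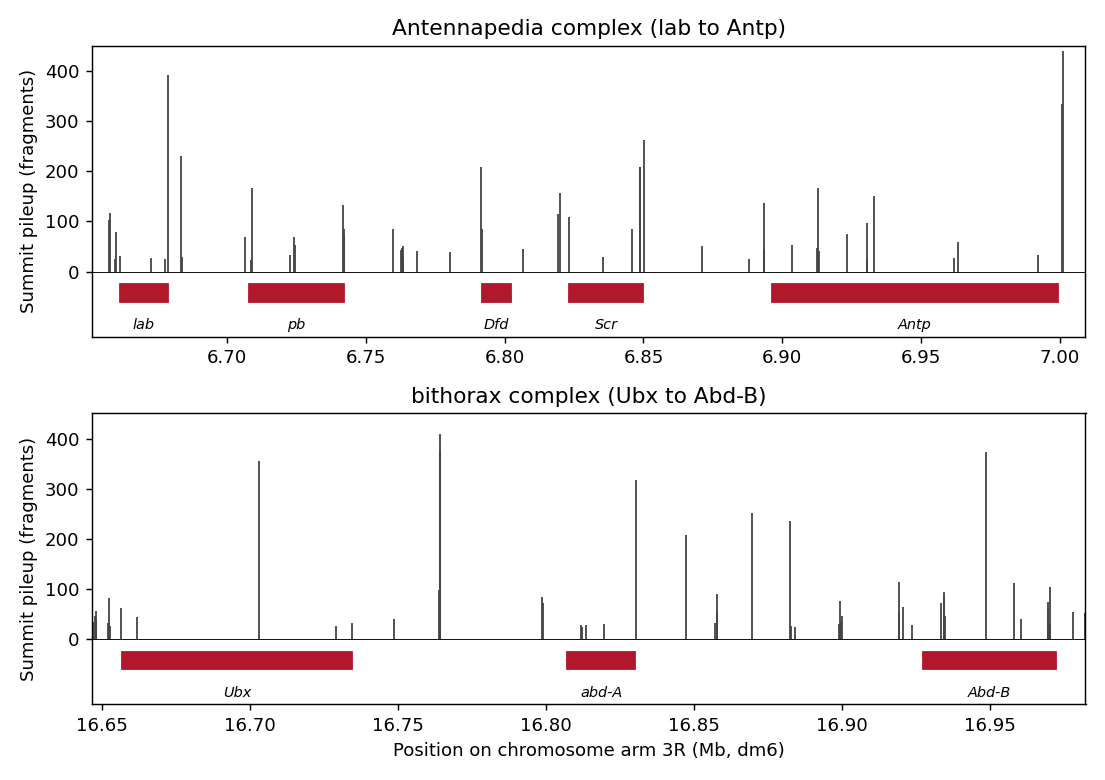
Summit pileup (fragments) along the Antennapedia and bithorax complexes on arm 3R (Mb, dm6), with 1 line per summit and the annotated homeotic genes as red boxes. The tallest lines include the right ends of lab (392) and abd-A (318), a summit 1781 bp past Antp (439) and a summit inside Abd-B (374).

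Both homeotic complexes held fewer accessible sites per length than the average of their arm. The Antennapedia complex, from lab to Antp (3R 6661427 to 6999228), had 47 summits, or 13.9 per 100 kb (95% Poisson interval 10.2 to 18.5), and the bithorax complex, from Ubx to Abd-B (3R 16656623 to 16972236), had 42, or 13.3 per 100 kb (9.59 to 18.0). The density of the whole arm was 26.2 per 100 kb. Low densities were common in windows of this size: the complexes lay at the 19.5th and 19.4th percentiles of 10000 random windows of their own lengths on 3R. Relative to the arm the Antennapedia density was 0.531, and it rose to 0.831 among peaks at or above the median fold.

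Long stretches without any peak occurred that shuffled summits did not give. Shuffled summits are spread evenly over an arm, so such stretches are near absent among them by construction. The contrast shows uneven spacing only and not its cause. Outside Y there were 110 stretches of at least 100 kb, together 22.5 Mb, against 0 in each of 1000 shuffles, whose longest was 84.0 kb. The longest, 944 kb, lay at 3R 2089151 to 3033493, and no protein-coding gene lay wholly inside it. Together with 6 such stretches on Y they held 605 protein-coding genes (4.34%), 19 of them on Y. Among the 605 were 15 of 60 gustatory and 9 of 60 ionotropic receptor genes, lists already found to lack peaks. Members can lie side by side, as Gr22a to Gr22e did in a stretch of 125 kb on 2L. The other lists called below had 7 of 59 odorant receptor, 4 of 21 testis, 1 of 14 follicle, 1 of 17 photoreceptor, 1 of 70 cuticle protein and 0 of 16 gut protease genes there. How much of this sequence could be mapped by reads was not measured here.

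The genes with the most accessible sites were long. The most summits lay inside kirre, a cell adhesion gene involved in myoblast fusion, with 78 in 394 kb. Sema1a, an axon guidance gene, had 74 in 130 kb, and bun, a TSC22-family transcription factor gene, had 74 in 91.1 kb. The ecdysone receptor gene EcR had 73 in 81.2 kb, and the ecdysone-induced nuclear receptor gene Eip75B had 70 in 114 kb. At the other end, CadN, a neuronal cadherin gene of 131 kb, had 1 summit inside, and cac, a calcium channel gene of 53.8 kb, had 0.

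The strongest summits by fold lay away from gene ends. The highest, with a fold of 103 and a pileup of 1207 (1140 to 1277), was at X 10283758, inside alpha-Man-Ia and 17.0 kb from its nearest end, in an interval of 63 bp. The next, 102-fold with a pileup of 2865, was at 3R 2088445 inside Myo81F, and the nearest gene end, of CR40182, lay 68.5 kb away. A summit at X 22433043, 11.2 kb from CG14621, had a fold of 85.1 and the highest pileup of the list, 3294 (3183 to 3409). The others of the strongest 10 were nearest to Pzl, CG46302, CCY, kl-5, CG10651, lncRNA:CR46106 and PRY, with folds from 57.3 down to 35.6. Of these 10 intervals 3 were on Y, and 0 had a summit within 250 bp of a gene end.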

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

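The tests on copy number of the 3L block and on narrow intervals were chosen only after their results had been seen in part; the test on the called peaks' own signal was set before. No biological explanation was tested, because the series has 1 group.

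Signal outside the comparisons appeared as a local background far above the genome-wide value. The highest, 328 fragments or 33.1 times the genome-wide 9.91, was in a block of 54 summits with a background of at least 60 on 3L from 606181 to 654352 that holds mir-ban, the microRNA gene bantam, and the next locus, around Rh5 on 2L, reached 160. If the called peaks themselves made up this background, their summed signal would reach it; an upper bound of that sum was 1.23 times the background (SD 0.355) in the block, which leaves this open. More copies of the block in the S2 genome may also raise summits and background alike: 33.3% of its summits (21.1 to 47.5%) were at 5-fold or more, against 29.9% at the other loci (Fisher's exact p = 0.639), so the 2 explanations cannot be told apart without coverage between peaks.

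The Y chromosome, which was left out of the comparison of X with autosomes, had 16 summits in 14 intervals, with pileups from 39 to 542 and a median of 124, and 1 of them at a gene end. Of the 10 strongest summits by fold 3 were on Y, nearest to CCY, kl-5 and PRY. The 10 strongest lay in intervals of 63 to 356 bp, with a median of 115.5 bp against 305.5 bp for the next 100 and 139 bp for the whole list, a difference from the next 100 of -190 bp (permutation p = 0.00029), and 0 of them were at gene ends against 55 of the next 100. Reads of repeated sequence piled on few positions are a candidate explanation, but the widths only restate the pattern and decide nothing, and the sequences were not examined.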

How the results depend on the processing

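No paired analysis was possible because the series has 1 group, and leaving out a library was not possible with 1 peak list. The enrichment at gene ends and the higher fold there kept their direction and their side of the threshold under each alternative run, with ratios to the shuffles from 1.78 (1000 bp) to 4.19 (100 bp), 2.27 with the local shuffle, and fold differences from 1.00 (median fold) to 2.77 (100 bp). The number of peaks was 20367 at a −log10 q of at least 10 and 17768 at or above the median fold. The share of protein-coding genes with a peak at an end was 53.1% and 51.3% under those thresholds, 53.8% and 71.9% with windows of 100 and 1000 bp, 57.8% with the summit inside the window and 30.3% at isolated ends. Wider windows and weaker peaks admit more genes by construction. The isolated setting scores fewer ends over a different set of genes. X minus autosomes turned to 1.88 points (exact p = 0.11) and 2.65 points (exact p = 0.024) under the stricter thresholds and 0.727 points at 100 bp (exact p = 0.54). It was -3.59 points at 1000 bp (exact p = 0.00069) and -3.07 points at isolated ends (exact p = 0.059). The cause was not tested, and the fold threshold selects on a ratio whose background is lower on X. Relative to 3R the Antennapedia complex had 0.722 and 0.831 of the arm's density under the stricter thresholds, and the bithorax complex 0.716 at the median fold, against 0.531 and 0.508 with all peaks; the cause was not tested.

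Of the 33 gene lists, 10 kept both direction and call under all 7 alternatives that can change them (merged lines cover the same bases). A list that had no call throughout but turned direction is not among these 10. Of 231 values 182 kept direction and call, 23 kept direction and lost the call, 12 kept direction and gained a call, and 14 turned direction. At isolated ends 8 lists were above and 3 below the other genes, with fewer genes tested. Antimicrobial peptides turned to 5.07 and 4.58 points (windows of 100 and 1000 bp), 1.07 (summit), 28.9 (matched lengths) and 12.6 (isolated ends). Glia turned to -2.20 (summit) and -6.18 (matched lengths), crystal cells and lamellocytes to -3.54 and heat shock to -1.75 (matched lengths). At isolated ends heat shock was at -5.32, fat body at 7.20, germline at -10.3, complex I at -19.2 and cytochrome P450 at 1.52; for these lists the cause was not tested. Of these only complex I had a call under the main settings. The motif alternatives and the 5′ start alternative were not run. Depth limits weak sites: at the lowest pileup of 20, just above the caller's threshold, a site is easily missed, and small lists such as the 8 PRC2 genes have wide intervals (63.1 to 100%).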

Other observations

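The tests of gene biotypes and of strength on X in this part were chosen after the data were examined; the X result at or above the median fold had been planned.

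Among genes that do not code for proteins, tRNA genes stood out. Of 290 tRNA genes, which RNA polymerase III transcribes, 241 had a peak at an end (83.1%, 78.3 to 87.2%), against 60.4% of protein-coding genes (adjusted p = 2.2e-16, Fisher's exact test over 8 classes), and the median pileup of those open was 160. The snRNA genes were at 62.5% (20 of 32, adjusted exact p = 0.86). Lower shares were found for antisense RNA genes (51.5%, adjusted exact p = 9e-05), lncRNA genes (27.1%, adjusted exact p = 3.9e-173), snoRNA genes (19.0%), miRNA genes (16.9%) and pseudogenes (15.3%). Annotated rRNA genes, a repeated family, had 1 of 98. Because tRNA genes are short and clustered, 1 peak can count for several of them. The 8 classes were not matched to protein-coding genes on length or position. An annotated gene end is not always a transcription start, so these shares do not compare promoters.

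With the block around mir-ban, 38 loci had a background of at least 60 fragments. They included ush (a GATA cofactor gene) with cbt at 138, pnt (an ETS gene) at 121, luna at 121, zfh2 at 121, HmgZ with HmgD (high mobility group genes) at 119, kay (the fly Fos gene) at 113, shn at 104 and aop (an ETS gene) at 81.1. Each locus joins summits with such a background that lie within 30 kb of each other: 56 such summits spanned 58.9 kb at ush and cbt and 26 spanned 17.9 kb at pnt, and other summits at these loci are not in the counts. Whether any class of genes is more common there than by chance was not tested.

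The longest peak-free stretches outside Y lay on 3R, 3L and 2R: 944 kb on 3R from 2089151, 867 kb on 3L from 26014329, 721 kb on 3R from 1364169, and 692 kb on 2R from 2856934, which holds Scp1 and dpr21. A stretch of 387 kb on 2L from 16941296 to 17327948 held 19 protein-coding genes, beat-IIIb among them. A stretch of 347 kb on 3L from 13513415 to 13860052 held Hml, a hemocyte gene. The right end of Hml at 13860001 lay just short of the peak that bounds the stretch. That peak is within 250 bp of this end, so Hml counted as a gene with a peak at an end.

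Fold enrichment at gene ends was higher on X than on the autosomes (5.50 against 5.21), while pileup was lower by a difference of -6.5 fragments (70.5 against 77, permutation p = 0.0014). The fold is the ratio of pileup to background, so a higher fold with a lower pileup goes with a lower background by arithmetic. The lower local background on X, 9.95 against 12.6, therefore restates the pattern and decides nothing about its cause. The lower pileup holds for gene ends only: over all summits the median pileup was 60 on X, above the 53 to 59 of the large autosome arms. The fold threshold that put X above the autosomes by 2.65 points selects on the same ratio.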
